A study of Drosophila melanogaster with 7 samples.

How the data were processed

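Total RNA from the salivary glands of crawling last-instar Drosophila melanogaster larvae was compared on 7 two-colour spotted oligonucleotide arrays of the INDAC FL003 design. Per the labels, every gland carried a heat-inducible TEV protease, an enzyme that cuts its own short recognition sequence. One sample of each pair had only a Rad21 protein with TEV sites. Rad21 is the subunit that closes the cohesin ring, so the protease opens the ring in these glands. The other sample of each pair had a Rad21 that the protease does not cut, from the genomic locus on 3 arrays (numbered 1.1, 1.2 and 1.3) and from a transgene on 4 arrays (numbered 2.1 to 2.4). Per the labels' protocols, glands were heat-shocked for 45 min at 37 °C and kept for 10 to 12 h at room temperature before RNA was isolated. The design text describes the 7 pairs as independently generated biological samples, so no sample entered 2 arrays. By the dye labels of the channels, the cleaved sample carried Cy5 on 4 arrays (1.1, 1.2, 2.1 and 2.2) and Cy3 on 3 arrays (1.3, 2.3 and 2.4). The series' design text gives these numbers the other way round, and the channel labels were used here.

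The values are the authors' deposited log ratios, read here as log2, 1 per probe and array, for 14569 probes with no missing value. Background correction, normalization, filters and probe averaging are not given in the sources used here, and the log base is not stated per the labels. The ratios were read as log2 because 2 deposited values exceed 11.1, the natural logarithm of the highest 16-bit scanner value. That value bounds a natural-log ratio only for unprocessed intensities of at least 1. Since the processing is not known, the base stays an assumption. If the base is another one, every size below is on that base, while signs and tests keep their values. Array medians lay between −0.22 and 0.25, so the arrays were not centred exactly on their medians. The 12 pairs of arrays with opposite dye orientation correlated between 0.011 and 0.481 (Pearson's r across probes, median 0.270), and by Spearman's rho 2 of them lay below 0 (2.1 with 2.3 at −0.0761 and 2.2 with 2.4 at −0.111). The 9 pairs of the same orientation correlated between −0.0414 and 0.587 (Pearson, median 0.394). Ratios left unturned would set opposite orientations against each other, so they were taken as already turned to one direction by the authors. No array was turned again.

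Which sample is the numerator is not stated, and the dyes do not settle it once the ratios are turned. Signs are therefore given as deposited. A negative ratio likely means less transcript in the glands with cleaved Rad21. The basis is outside the labels: cohesin mutant fly neurons are known from other work to have less ecdysone receptor, and the receptor gene EcR was negative on all 7 arrays here. Every statement on signs keeps its count and size if the true direction is the opposite.

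Probes were named through the platform's probe annotation, updated with the NCBI RefSeq gene table of the Release 6 assembly, by Entrez gene number for 12011 probes, accession for 107 and synonym for 500, with the file's symbol kept for 39. In total 12657 probes had 1 gene symbol (11609 genes, 693 of them with more than 1 probe), 96 had several and 1816 had none. Probes with several or no symbols were tested but not named. The gene table gave chromosome arms and the order of genes. None of its coordinates are printed, since the build behind the probes is not given in the sources used here. Genes without a named probe, among them vtd (which encodes Rad21), Eip74EF, Eip75B, Sgs3, Sgs7 and Sgs8, were not analysed here. The same holds for rpr, hid, Diap1 and Drice of the apoptosis list and Cdk1, CycA, stg and polo of the mitosis list. It also holds for the Hox genes Ubx, abd-A and Abd-B, the fat body genes Lsp1alpha, Lsp1beta and Lsp1gamma, and 13 immune genes. Each list result below covers the measured members only.

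Each probe was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the effect of cleavage and a gene-wise dye term, and tested against 0 with Benjamini-Hochberg adjustment over all probes at an adjusted p under 0.05. The fit left 5 residual degrees of freedom, to which eBayes added 3.04. The dye term passed its own test for 0 probes. The difference between the 2 sets of arrays was tested in a fit with an effect for each set and the same dye term. Gene lists were tested on gene means of probes with camera at an inter-gene correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation and with fry. The lists covered cohesin and its regulators, ecdysone regulators, other ecdysone-induced genes, glue genes, late 71E puff genes, heat shock genes, apoptosis, autophagy, DNA replication, mitosis, cytosolic and mitochondrial ribosomal proteins, proteasome subunits, ribosome biogenesis, the secretory pathway, Polycomb group genes, Hox genes with other cohesin-studied loci, glycolysis, immune genes, glutathione transferases, and markers of fat body, hemocytes, muscle, cuticle, gut and nervous system. Chromosome 3, which carries Rad21, was set against the other chromosomes with a two-sided Fisher's exact test and a 95% interval.

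The tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took 1 probe per gene (the smallest unadjusted p), and named the 12 largest log2 ratios in each direction with an adjusted p under 0.05 and the same sign on 7 arrays. It also named every measured member of the cohesin and ecdysone regulator lists, and of each other list up to 4 members past the test. Alternatives were median centring, centring with scaling, no dye term, array weights, robust eBayes, a set term, each set alone, each array left out, averaged probes and other thresholds. Leaving out some probe groups and centring within probe groups were added after seeing the data. Those groups share the 11th and 12th digits of the probe number, which appear to follow the position of the spots, although no source used here states this.

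The fit was tested on simulated data with 200 changed probes among 14569, in 5 runs. Of probes changed by 1 on the log2 scale 38% were recovered, and of those changed by 2, 84.6%, with 6.2 false calls per run. For the difference between sets, 0% was recovered at either size. The Benjamini-Hochberg cutoff depends on how many probes change, and 1158 passed in the data. The recovered shares hold for the simulated number and are not those of the data. Spot intensities were not used here, so signal over background was not assessed. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.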

Results

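The data compare glands whose cohesin ring was opened by protease with glands whose ring stayed intact, in a tissue that is terminally differentiated. The question was which transcripts differ when cohesin is lost from cells that no longer divide. Each of the 7 arrays gave log2 ratios for 14569 probes between 1 sample of each kind. The intact sample had genomic Rad21 on 3 arrays and transgenic Rad21 on 4. The share of probes with an absolute log2 ratio above 1 ran from 6.02% on array 1.2 to 27.3% on array 2.1. Signs are given as deposited, and the direction they stand for is likely, not settled, as described for the processing. The glands with cleaved and intact cohesin also came from different fly stocks, so a stock difference and Rad21 cleavage cannot be told apart.

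Between cleaved and intact cohesin, 1158 of 14569 probes changed, 554 with negative and 604 with positive log2 ratios (limma, adjusted p under 0.05). These probes named 964 distinct genes. The most negative was Sgs1, which encodes a protein of the salivary glue, at −6.21 ± 0.31 (SE, n = 7 arrays, adjusted p = 9.12e-05 with limma). CG10237 followed at −5.60 ± 0.34, then Eig71Eg of the ecdysone-induced 71E puff at −4.96 ± 0.53 and Drsl5, of the drosomycin family of antifungal peptides, at −4.65 ± 0.51. Eig71Ef of the 71E puff lay at −4.59 ± 0.88, the zinc transporter gene Zip88E at −3.98 ± 0.21, and the lysosomal membrane protein gene Cln3 at −3.82 ± 0.17. The other 5 most negative genes, CG31698, Prosap, hoe2, CG15404 and CG9040, lay between −3.84 and −3.53. The most positive was Mst87F, a gene known for its transcript in the male germ line, at 5.74 ± 0.35 (adjusted p = 0.000191 with limma). Npc2e, of a family of sterol-binding proteins, lay at 5.37 ± 0.40, and obst-H, of a chitin-binding family, at 4.79 ± 0.39. Obp99d, an odorant-binding protein gene, reached 4.61 ± 0.27, wbl, an endoplasmic reticulum protein gene, 4.24 ± 0.21, and the cytochrome P450 gene Cyp4e3 4.07 ± 0.47. CG14062, Ag5r, CG12546, yip3, CG12535 and NaPi-III lay between 3.55 and 4.32. Each of these 24 genes had the same sign on 7 of 7 arrays, which the rule for naming them required. Among them, Eig71Ef lost its call without array 1.3, 2.2 or 2.4 (limma adjusted p 0.0521 to 0.0831).

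Of the changed probes, 1001 had the same sign on 7 arrays, and the median absolute log2 ratio of the changed probes was 1.01. The median over all probes was 0.02. With the probes of each gene averaged, 945 of 11609 genes changed, 444 negative and 501 positive. The count fell to 724, 578, 661 and 515 probes without array 1.1, 1.2, 2.1 or 2.4. It was 389 at an adjusted p under 0.01, and 594 when an absolute log2 ratio of at least 1 was also asked for.

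**Figure D1:**
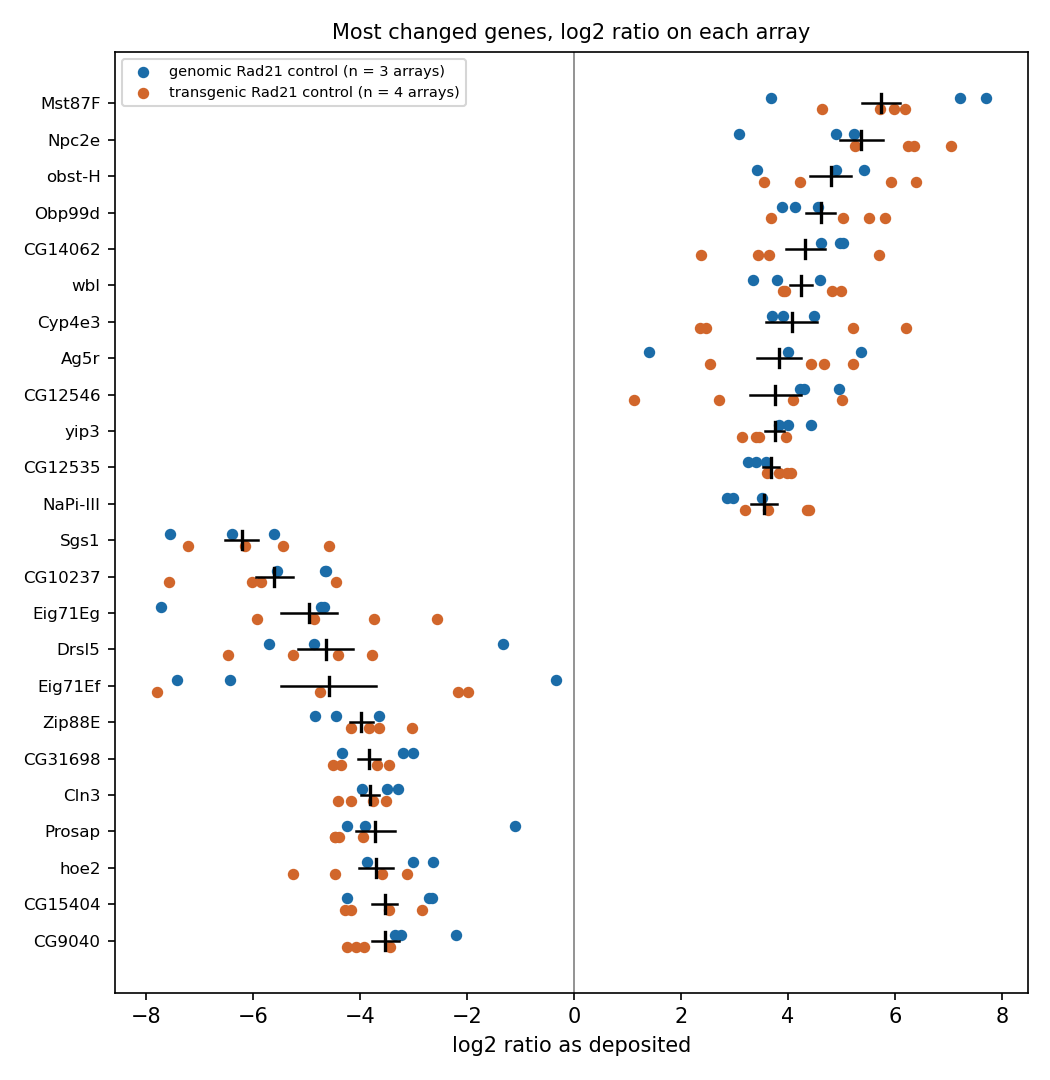
Log2 ratios as deposited (horizontal axis) of the 12 most positive and 12 most negative genes, with a point for each array, blue for the genomic Rad21 control (n = 3) and orange for the transgenic Rad21 control (n = 4), and the fitted value ± SE in black. Every point of a gene lies on the same side of 0, as the rule for choosing these genes required, from −7.81 for Eig71Ef on array 2.4 to 7.70 for Mst87F on array 1.2.

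Of 14 measured regulators of the response to the steroid hormone ecdysone, 4 had negative and 1 positive log2 ratios past the test, and 9 did not pass. The receptor gene EcR lay at −1.77 ± 0.17 (SE, n = 7, adjusted p = 0.00111 with limma) and was negative on 7 of 7 arrays. The early-response transcription factor gene br lay at −1.81 ± 0.16 for the leading of its 6 probes, and all 6 were negative, between −1.81 and −0.45, with 3 of them past the test. The nuclear receptor gene Eip78C lay at −2.96 ± 0.47, negative on 6 of 7 arrays, and vri at −1.08 ± 0.22. The nuclear receptor gene ftz-f1 was the positive one, at 0.78 ± 0.19 (adjusted p = 0.045 with limma). Among the members not past the test, Hr39 lay at −0.76 ± 0.22 (adjusted p = 0.0818), Cyp18a1 at −0.44 ± 0.21, Hr3 at 0.42 ± 0.32, Eip93F at −0.36 ± 0.31, Hr4 at −0.28 ± 0.26, E23 at −0.18 ± 0.26, Hr38 at 0.10 ± 0.22, Kr-h1 at 0.08 ± 0.21 and usp at 0.05 ± 0.17 by limma. Adjusted over the list alone, 5 were negative (with Hr39) and 1 positive. The list's median was −0.31 (camera adjusted p = 0.0312), and the list did not pass with adjusted p = 0.789 with an estimated correlation. The call of vri was lost without array 1.2, 1.3 or 2.4 (limma adjusted p up to 0.082), and that of ftz-f1 without any array except 2.2 (up to 0.133). On all 7 arrays ftz-f1 also lost its call with median centring (limma adjusted p = 0.0785), centring with scaling (0.0660), a set term (0.0687) or centring within probe groups (0.169). The list's call was lost without array 2.4 (median −0.05, camera adjusted p = 0.0511), without the dye term (0.0581) or on the transgenic Rad21 arrays alone (0.0509).

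The late genes of the 71E puff, which ecdysone induces in this tissue, were the most negative list, with a median of −1.99 over 8 measured members (camera adjusted p = 1.32e-05, and adjusted p = 0.789 with an estimated correlation). Eig71Eg, Eig71Ef and Eig71Ed (−3.74 ± 0.90) passed the test over all genes, and 5 did not. Adjusted over the list alone, 7 were negative, among them Eig71Ea at −2.49 ± 0.66 and Eig71Eh at −1.50 ± 0.44. The list's median ran from −3.82 on array 1.3 to 0.13 on array 1.2, the only array where it was positive. Eig71Ed also lost its call without array 1.1, 1.3, 2.1, 2.2 or 2.4 (limma adjusted p up to 0.151).

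Of 10 measured glue and intermoult genes, which the gland makes before puparium formation, 2 were negative past the test, Sgs1 and Eig71Ee (−0.80 ± 0.20, adjusted p = 0.0465 with limma), and 8 did not pass. Adjusted over the list alone, 3 were negative, with Sgs5 at −1.06 ± 0.29. The list's median was −0.29 (camera adjusted p = 0.0352, and adjusted p = 0.789 with an estimated correlation). The list's call was lost without array 1.3 (median −0.17, camera adjusted p = 0.0656), 2.2 (−0.24, 0.255) or 2.3 (−0.45, 0.174). It was also lost on the genomic Rad21 arrays alone (0.306), with arrays scaled (0.150), array weights (0.244), no dye term (0.0581), a set term (0.0700) or centring within probe groups (0.0599), and that of Eig71Ee without any array except 1.1. Of 10 other ecdysone-induced genes, 1 gene mean passed the test, ImpE3 at 1.45 ± 0.22, and 9 did not (median −0.05, mean 0.09, camera adjusted p = 0.889, 1 adjusted over the list alone). The leading of the 3 ImpL2 probes lay at −0.76 ± 0.16 (adjusted p = 0.0294 with limma), while another lay at 0.57 ± 0.20, so the probes of this gene disagreed, and its call was lost without any array except 1.2 (adjusted p up to 0.0829).

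Secretory pathway genes, which build the route by which glue and other proteins leave the cell, had a median of −0.72 over 21 measured members (camera adjusted p = 8.71e-06, and adjusted p = 0.789 with an estimated correlation). Of these, 8 were negative past the test and 13 did not pass. The list's median was −0.03, −0.83 and −0.27 on arrays 1.1, 1.2 and 1.3, and −0.69, −1.22, −1.38 and −0.09 on arrays 2.1 to 2.4, so the arrays differed widely. The translocon genes TRAM, Sec61alpha and Sec61beta lay at −1.29 ± 0.21, −1.27 ± 0.22 and −0.97 ± 0.19, and sage, a transcription factor of the salivary gland, at −1.13 ± 0.17 (SE, n = 7, limma adjusted p between 0.00844 and 0.0218). The others past the test were KdelR (−0.89), Sec61gamma (−0.84), gammaCOP and betaCOP (both −0.81). Adjusted over the list alone, 12 were negative and 1 positive, PH4alphaSG1 at 1.25 ± 0.36, a prolyl hydroxylase of the gland. On the genomic Rad21 arrays alone the list did not pass (median −0.36, camera adjusted p = 0.073), and without array 2.3 its median was −0.43. Sec61beta lost its call without array 1.2, 1.3, 2.1, 2.2 or 2.4 (limma adjusted p up to 0.0741), and sage and Sec61beta with arrays scaled.

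Mitochondrial ribosomal proteins had a median of −0.22 over 69 genes (camera adjusted p = 4.93e-05, and adjusted p = 0.789 with an estimated correlation). Split by symbol after the data were seen, the 43 mRpL genes of the large subunit had a median of −0.25 (camera adjusted p = 5.83e-05 over 59 families, and 0.999 with an estimated correlation) and the 25 mRpS genes of the small subunit −0.03 (0.409), and the difference was not tested. Of the 69 genes, 3 were negative past the test, mRpS33 (−0.85 ± 0.13), mRpL36 (−0.81 ± 0.14) and mRpL46 (−0.73 ± 0.14), as were 3 adjusted over the list alone, and 66 did not pass. The call of mRpL46 was lost without array 1.2, 1.3 or 2.4. For the 34 cytosolic ribosomal proteins, 0 genes passed (median −0.15, camera adjusted p = 0.127), and so it was for 14 ribosome biogenesis genes (median −0.21, adjusted p = 0.0509), with 0 in both adjusted over the list alone by limma. The cytosolic list passed camera without array 2.3 (adjusted p = 0.0448) or 2.4 (0.0287) and on the genomic Rad21 arrays alone (−0.31, 0.00892), where its median was −0.72 on array 1.3 but 0.15 on array 1.1 and −0.00 on array 1.2. The biogenesis list passed without array 1.1 (0.0322), 1.2 (0.0457), 1.3 (0.0225) or 2.4 (0.0121), with a set term (0.0494) and on the transgenic Rad21 arrays alone (−0.36, 0.00673). On all arrays with an estimated correlation the adjusted p was 0.927 for the cytosolic and 0.789 for the biogenesis list.

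**Figure D2:**
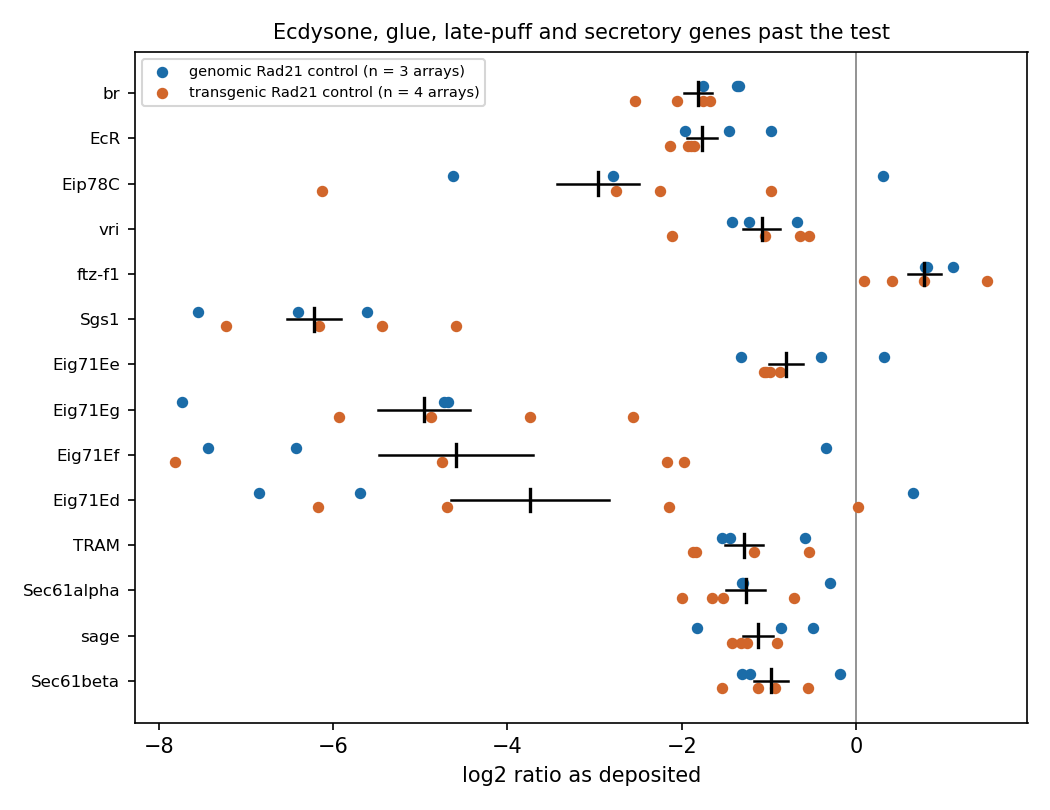
Log2 ratios as deposited (horizontal axis) of the named ecdysone, glue, late 71E puff and secretory genes past the test, with a point for each array (blue, genomic Rad21 control, n = 3, and orange, transgenic Rad21 control, n = 4) and the fitted value ± SE in black. The Eig71Ef and Eig71Ed points spread most, from −7.81 to −0.34 and from −6.85 to 0.65, while EcR stays between −2.14 and −0.98.

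None of 10 measured cohesin subunits and regulators passed the test over all probes, and 0 did when adjusted over the list alone (limma; median −0.05, camera adjusted p = 0.698). The acetyltransferase gene eco lay at −0.37 ± 0.15 (SE, n = 7), SA1 at 0.23 ± 0.13, SMC1 at −0.21 ± 0.13, Nipped-B at −0.17 ± 0.23, wapl at −0.16 ± 0.13, pds5 at −0.06 ± 0.14 and san at −0.03 ± 0.16. SMC3 (0.28 ± 0.29), dmt (0.19 ± 0.30) and Mau2 (−0.01 ± 0.35) were spread by array 1.3, where they read 2.57, 2.06 and 2.15. The protease acts on the Rad21 protein, so a transcript level does not check the cleavage. The gene for Rad21 was not analysed here.

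Heat shock genes, which both samples of a pair would have induced, had 1 of 9 past the test, the co-chaperone gene stv at 0.88 ± 0.21 (also 1 adjusted over the list alone), while the list's median was −0.40 (camera adjusted p = 0.284). Of 16 autophagy genes 1 passed, Atg13 at −0.96 ± 0.22 (1 adjusted over the list alone, median 0.05, adjusted p = 0.889). Of 11 Polycomb group genes 1 passed, phol at 0.66 ± 0.12 (2 adjusted over the list alone, with Psc at 0.65 ± 0.18, median −0.04, adjusted p = 0.889). Of 28 glutathione transferases 1 was positive, GstT4 at 1.71 ± 0.34, and 1 negative, GstZ2 at −1.92 ± 0.35 (2 positive and 4 negative adjusted over the list alone, median −0.02, adjusted p = 0.889). Of 10 immune genes Drs was negative at −1.73 ± 0.23 and PGRP-LF positive at 1.58 ± 0.40 as a gene mean (adjusted p = 0.0496 with limma), with 3 positive and 1 negative adjusted over the list alone (median 0.37, adjusted p = 0.889). Of 40 genes matched by name as proteasome subunits only Prosap passed (median 0.11, adjusted p = 0.614, 1 adjusted over the list alone), and Prosap encodes a synaptic scaffold protein, not a subunit. None passed in the limma test, over all genes or adjusted over the list alone, among 11 apoptosis genes (median −0.07, camera adjusted p = 0.218), 20 DNA replication genes (−0.22, 0.0926), 15 mitosis genes (−0.17, 0.142), 9 glycolysis genes (−0.25, 0.187) and 14 Hox genes and cohesin-studied loci (0.03, 0.889). Calls of stv, Atg13, phol and GstT4 were each lost without 5 or 6 of the single arrays and that of GstZ2 without array 2.4, the DNA replication list passed camera without array 1.1 (adjusted p = 0.00518), 1.3 (0.0435) or 2.4 (0.0146) the glycolysis list without array 1.1 (0.0322) or 2.4 (0.0265), and the proteasome list without array 1.3 (0.00644). On the transgenic Rad21 arrays alone the DNA replication (median −0.51, camera adjusted p = 0.000523), proteasome (0.39, 0.000523) and glycolysis (−0.34, 0.0295) lists passed, and on the genomic Rad21 arrays alone the heat shock (−0.61, 0.00977) and proteasome (−0.24, 0.000224) lists, the last with the opposite sign. On all arrays with an estimated correlation the adjusted p was 0.927 for DNA replication and glycolysis, 0.946 for the proteasome and 0.789 for heat shock. The proteasome list's median was −0.76 on array 1.3 but 0.20 on array 1.1 and 0.06 on array 1.2. The median and the mean differed in sign for the proteasome (mean −0.00), Polycomb (0.02) and glutathione transferase (0.04) lists.

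Markers of tissues that could be dissected with the gland did not pass as lists on all 7 arrays. Fat body (6 genes) had a median of 0.02 (camera adjusted p = 0.889), hemocytes (12 genes) 0.03 (0.579), muscle (10 genes) −0.13 (0.187), cuticle (15 genes) 0.00 (0.889), gut (22 genes) −0.14 (0.301) and nervous system (12 genes) −0.08 (0.889). Single members passed, namely the lipid transfer protein gene Apoltp at 0.91 ± 0.19, the GATA cofactor gene ush at 3.29 ± 0.16, the troponin gene TpnC73F at −1.15 ± 0.20 and the ion pump subunit gene nrv2 at 1.34 ± 0.13 (limma, 7 of 7 arrays each). Adjusted over the list alone, each of these was called in its list, Fbp1 was also called in the fat body list at −1.10 ± 0.32, and 0 were called for cuticle and gut. Apoltp lost its call without array 1.1, 1.2, 1.3, 2.1 or 2.4, TpnC73F without array 2.4, and the gut list passed camera without array 2.3 (median −0.37, adjusted p = 0.0444) and on the genomic Rad21 arrays alone (−0.16, 0.000224). The muscle list passed on the transgenic Rad21 arrays alone (−0.35, 0.0295). On all arrays with an estimated correlation the adjusted p was 0.946 for gut and 0.789 for muscle. The mean was −0.01 for fat body and 0.00 for the nervous system, of the other sign than the median.

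Changed genes were spread over the chromosomes, with 7.16% of genes on X, 8.01% on 2L, 8.44% on 2R, 9.18% on 3L, 7.88% on 3R and 4.84% of the 62 genes on chromosome 4. On chromosome 3, which carries Rad21 and the crossed alleles, 8.45% of genes changed, against 7.89% elsewhere (odds ratio 1.08, 95% interval 0.941 to 1.23, two-sided Fisher's exact test p = 0.274). With genes past an adjusted p under 0.01 the odds ratio was 0.923. Fisher's test takes genes as independent, while changed neighbours shared a sign more often than permuted calls did, as described below. The interval may therefore be too narrow.

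The second comparison asked whether the change depended on the kind of control, genomic or transgenic Rad21. Across probes, the mean log2 ratios of the 2 sets, which share no sample, correlated with Pearson's r of 0.592 and Spearman's rho of 0.433, where probes are not independent replicates. No probe differed between the sets in limma at an adjusted p under 0.05 (0 probes, with 621 at an unadjusted p under 0.05, and 1 without the dye term). With 200 probes simulated to differ by 2 on the log2 scale, none was recovered, and other numbers of differing probes were not simulated. The count of 0 therefore does not show that single genes lack differences of that size. EcR, named for its list and not for its signs, was negative on each array of both sets. Fitted alone, the 3 genomic Rad21 arrays gave 2781 changed probes and the 4 transgenic Rad21 arrays 39, counts that do not test the difference. The 50 named genes past the test were chosen on all 7 arrays. Of these genes, 16 passed on the transgenic Rad21 arrays alone, among them Sgs1, Mst87F, Cln3 and ush. EcR, br and Eip78C did not pass there, at −1.95, −2.01 and −3.03 (limma adjusted p 0.0672, 0.0818 and 0.174). The genomic Rad21 set has 1 array with the cleaved sample in Cy3. With the dye term that array is fitted exactly, so the calls of that set alone do not measure replication.

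**Figure D3:**
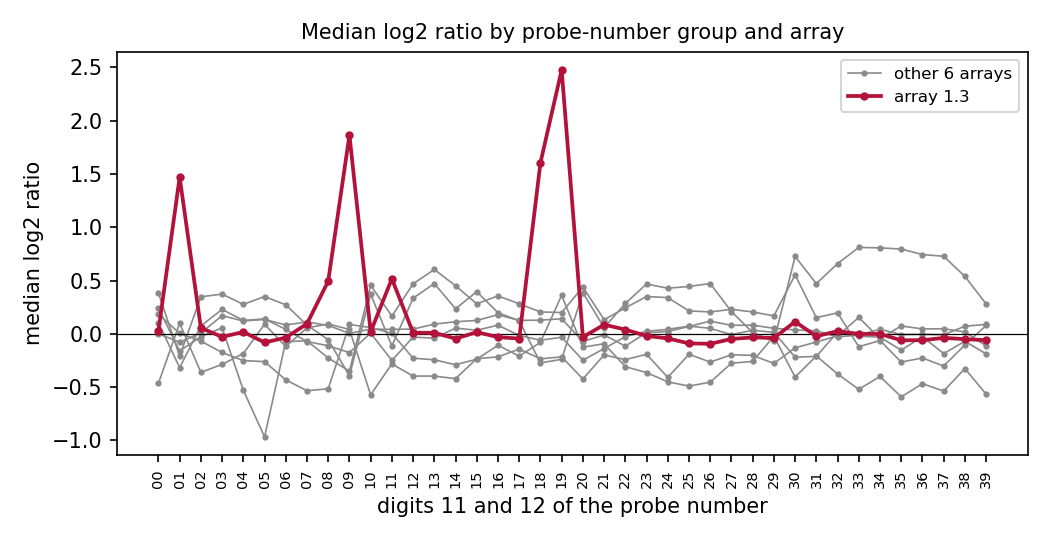
Median log2 ratio (vertical axis) of the probes that share the 11th and 12th digits of their probe number (horizontal axis), with a line for each array, array 1.3 in red and the other 6 in grey. On array 1.3, 6 of the 40 groups stand above 0.4, up to 2.48, and the others lie between −0.09 and 0.11.

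The genes SMC3, dmt, Mau2 and Prosap belonged to a set of 3094 probes that read high in median on array 1.3. So did Mst87F, Obp99d, CG14062, wbl and Cyp4e3 of the most positive genes and CG31698 and CG9040 of the most negative. Among other named genes past the test, so did ush, sage, TRAM and Atg13. Of these further genes only sage had its highest value on array 1.3 (−0.49). In 6 of 40 groups of probes that share digits of the probe number, the median of that array was 1.08, against −0.01 in its other groups. Without these groups, 1114 of the remaining probes changed in limma, 551 negative and 563 positive, and the same 5 lists passed camera, none of which passed on all probes with an estimated correlation (adjusted p = 0.789) or with fry.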

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

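The counts over other splits of the arrays and the tests of why array 1.3 differed were chosen only after the results were seen, except that the share of positive calls and the comparison within genes were set down before those values, though after the pattern on array 1.3, had been seen.

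Prosap, which encodes a synaptic scaffold protein, stood out for 1 array apart from the others of the transgenic Rad21 set. On array 2.4 its log2 ratio was −3.95, while the other 3 transgenic Rad21 arrays lay between −4.47 and −4.39. It was the only 1 of 95 named genes and lists set apart within these 4 arrays, and the 95% limit used sets apart about 1 in 20 by chance. The 3 genomic Rad21 arrays were not examined in this way, and there Prosap read −3.91, −4.25 and −1.11, a wider gap on array 1.3 than on array 2.4. SMC3 (−0.40, −0.41 and 2.57) and Mau2 (−0.23, −0.24 and 2.15) were also apart on array 1.3.

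More probes changed between cleaved and intact cohesin with the real signs than with any other signs tried, which does not exclude chance. Of the 63 ways to turn the signs of the arrays that the dye term allows, 1, the real one, gave as many as 1158 probes. The highest other count was 321, with arrays 2.3 and 2.4 turned. The signs were kept as deposited because of the correlations between arrays, which favoured the real signs in advance. Turning every array with the cleaved sample in Cy3 was not among the 63 ways, because it exchanges the effect of cleavage with the dye term. Had the ratios been deposited unturned, the 1158 probes would be dye effects, and the count cannot tell these readings apart. For the difference between the sets the splits decide nothing, because any split gives at least the real count of 0 probes (limma, 621 at an unadjusted p under 0.05), as all 34 splits into 3 and 4 arrays that the dye term allows did. The highest other count was 97, for arrays 1.1, 1.2 and 2.2 against the rest. With the dye term, that split sets array 2.1 alone against the other arrays of its dye orientation. The count thus rests on 1 array, the one with the largest SD over all probes (1.18).

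On array 1.3, 3094 probes in 6 of 40 groups by probe number, among them those of SMC3, dmt and Mau2, had a median log2 ratio of 1.08, against −0.01 in the other groups, and held 438 of the 467 values above 3. On array 2.1 these groups held 75 of the 117 values above 3 and lay 0.249 above the others in median, so a weaker form of the pattern was present there too. Groups by probe number also differed in other ways on other arrays. Their medians ran from −0.97 to 0.60 on array 2.2 and from −0.39 to 0.81 on array 2.3. On array 2.3 the difference of these 6 groups from the others was −0.55. A change of these genes against the genomic Rad21 control is argued against, because on arrays 1.1 and 1.2 the same probes lay below the others (the larger difference −0.0306), and so is dye orientation, with a larger difference of 0.0970 on arrays 2.3 and 2.4. Spot position on that slide stays open as a candidate explanation. Among 233 genes with probes inside and outside these groups, the inside probes lay 1.03 higher in median on array 1.3 (189 genes higher), against −0.53 to 0.08 on the other 6 arrays. Of the 2781 calls on the genomic Rad21 arrays alone 70.7% were positive, and of 1102 calls with these groups left out 48.2%. The groups were picked because they read high on array 1.3. The fall therefore shows where the excess of positive calls lay and not its cause.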

How the results depend on the processing

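The alternatives without the raised probe groups and with centring within probe groups were chosen after seeing the data. Of the 50 named genes past the test, 0 changed sign under the alternatives run, 35 kept their call with each array left out, 37 under the other alternatives on all arrays, and 34 under both. Without 1 array at a time the count of changed probes ran from 515 to 1157 (negative 249 to 546, positive 266 to 611), the correlation between the sets from 0.484 to 0.651, and the lists past camera from 4 to 8. The genomic Rad21 arrays alone gave 2781 probes (1965 positive), and the transgenic Rad21 arrays alone 39 (21 negative, 18 positive), with fewer arrays in each. An adjusted p under 0.01 gave 389 (192 negative, 197 positive) and an odds ratio of 0.923 for chromosome 3, and a log2 ratio of at least 1 gave 594 (291 negative, 303 positive), as a stricter threshold must give fewer. Without the dye term 1 probe differed between the sets and 3 lists passed. On the transgenic Rad21 arrays alone 9 lists passed camera. On all 7 arrays 0 passed with an estimated correlation and 0 with fry. On the genomic Rad21 arrays alone the proteasome list turned to −0.24 and Mau2, which read 2.15 on array 1.3, to 0.96. That fit weighs array 1.3 as much as arrays 1.1 and 1.2 together. Its residuals come only from the difference between arrays 1.1 and 1.2. Its counts of calls are therefore not comparable with those of the transgenic Rad21 arrays. The proteasome median was −0.76 on array 1.3, against 0.20 on array 1.1 and 0.06 on array 1.2. The list and Mau2 thus turned with array 1.3. For the list counts the cause was not tested. Among the further values of single genes, 998 stayed, 127 lost their call, 3 gained it and 26 moved. Among those of lists, 407 stayed, 23 lost their call, 22 gained it and 41 moved. Alternatives for missing values were not run because no value was missing. Spot intensities were not used here, so what signal over background limits was not assessed.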

Other observations

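The gene families, the neighbouring genes and the tests of the spread of the 71E genes between arrays were chosen only after the results were seen, although the tests of neighbours by spot position, relatedness and overlap were set down before their values were known.

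Among 59 families of at least 10 genes that share a symbol stem, mitochondrial complex I was negative, with a median of −0.29 over 31 genes (camera adjusted p = 7.35e-05, and 0.999 with an estimated correlation). Of these, 6 passed the limma test, ND-13A, ND-18, ND-19, ND-B17, ND-B18 and ND-PDSW. Of 17 vacuolar ATPase genes 5 were negative past the test, among them Vha36-1 at −0.99 and Vha55 at −0.94, while the family did not pass (adjusted p = 0.0741). Of 35 UDP-glycosyltransferase genes 2 were positive, Ugt37C1 at 2.59 and Ugt317A1 at 1.35 (family median 0.17, adjusted p = 0.0316, and 0.999 with an estimated correlation). The antimicrobial peptide genes Def and AttD did not pass the limma test (3.15 ± 0.91, adjusted p = 0.0789, and 2.62 ± 0.79, adjusted p = 0.0916, n = 7). On arrays 1.1, 2.1, 2.2 and 2.4 Def read 4.99, 6.25, 4.57 and 6.44 and AttD 4.60, 3.34, 4.21 and 5.95, and on arrays 1.2, 1.3 and 2.3 Def read 0.65, −0.16 and 0.30 and AttD 0.09, 0.17 and 0.44. Whether other antimicrobial peptide genes follow the same arrays was not tested. DptB read 2.58, −1.57, 2.21, 1.86, −1.31, −1.02 and 4.61 on arrays 1.1 to 2.4 in order, Mtk was negative on 7 of 7 arrays (−0.77 ± 0.36, limma adjusted p = 0.284), and AttB lay at −0.24 ± 0.19.

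Changed genes with the same sign lay next to each other on the chromosome more often than permuted calls placed them, with 79 pairs against 38.5 (2.05 times, permutation p = 1e-05, the smallest that 100000 permutations can give). Examples are Eig71Ed, Eig71Ee, Eig71Ef and Eig71Eg, ATP6AP2, sage and TrpRS, all negative, and heca, Fer1HCH and Fer2LCH, positive at 0.80, 0.75 and 0.69. The ratio was 1.97 without pairs that share a probe group, 1.95 (72 pairs) without pairs that share a symbol stem, and 1.95 (62 pairs) without overlapping genes. This argues against a shared probe group, named relatives and overlap as the whole cause. Pairs with probes in different groups were kept, so a position effect wider than a group was not tested. Genes known by CG numbers can be related without sharing a stem, and with named genes alone the ratio was 2.02 (24 pairs, permutation p = 0.0013). Without pairs on chromosome 3 the ratio was 1.99 (40 pairs, permutation p = 5e-05). Stock differences, on any chromosome, cannot be told apart from cleavage here. The design gives no biological explanation and none was tested.

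The late 71E puff genes, Eig71Ed and Eig71Ef among them, spread widely between arrays, with list medians from −3.82 on array 1.3 to 0.13 on array 1.2. Compressed ratios on array 1.2 are argued against, although this array had the smallest SD over all probes (0.55). The 575 probes other than 71E that changed without array 1.2 kept a median 0.846 of their fitted value on it, which is 0.998 times the median share of the other 6 arrays, each read in the same way. Dye orientation is argued against by overlapping values, with a mean difference of 0.590. Sample pairs at different points of the ecdysone response may differ in this way, but this stays open. The 9 regulators that did not pass the test over all probes, with Hr39 among them, gave, against the list, a Pearson's r of 0.381 over 7 arrays (exact permutation p = 0.405, and 0.662 adjusted over 2 relations), and r was −0.105 without arrays 1.2 and 2.3.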
